A study of Caenorhabditis elegans with 2 samples.

How the data were processed

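The data are peak lists from chromatin immunoprecipitation of an eGFP fusion of C16A3.4 in L1 larvae, from 2 samples that the labels call biological replicates 1 and 2. All samples form 1 group. The labels give no treatment and no second condition. Per the notes deposited beside the lists, the authors called peaks on each replicate's alignments with a control, on both replicates' alignments together with the same control, and then derived a thresholded list from the pooled and replicate lists by the irreproducible discovery rate (IDR), a measure of how consistently peaks rank between replicates. The resulting list equals the 3220 strongest pooled peaks, so it also holds peaks that rank differently in the replicates or are missing from 1 of them. Each of the 4 lists exists on 2 genome builds, ce10 and ce11, which makes 8 lists. The aligner, the peak caller, their versions and their settings are not given in the sources used here.

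The first measurement of each peak is the authors' signal value, on a scale that is not stated. It was treated here as an enrichment value. The second is the −log10 q value that the authors deposited in the narrowPeak q column, with a tied highest value in each list. The summit is the deposited offset from the peak's start, and it lay at the exact centre of 83.9% of the thresholded peaks. The signal was used to describe, rank and select peaks within a list, and at matched peaks the values of the replicates and of the pooled list were set side by side as if on 1 scale. The replicate lists are relaxed lists of peaks and background, 30000 peaks each, so only their strongest peaks were set side by side. The files used here hold no read counts, so depth per sample is unknown, and Wilson 95% intervals on shares of peaks cover counting error only. At their list's highest q sat 2552 peaks of replicate 1 and 3745 of replicate 2, and whether their depths differed is unknown.

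Peaks on ce11 were placed on the reference genome WBcel235, which is the same assembly, with the Ensembl release 115 annotation (46890 genes, 19973 of them protein-coding) on the 6 nuclear chromosomes. Lists on ce10 were used for counts and comparisons within that build. The promoter window ran from 1000 bp upstream to 200 bp downstream of a gene's annotated 5′ end. Many worm transcripts are trans-spliced or come from operons, so the annotated end can lie away from where transcription starts. Summits outside the windows of protein-coding genes were classed in turn as exon, intron, non-coding gene or intergenic. Positions were compared with 1000 random placements on the same chromosome. Random placement treats all sequence as equally readable, which repeats are not.

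Summits of the replicates were matched within 100 bp. Gene lists, 27 of protein-coding genes and 6 by RNA type, were tested with Fisher's exact test against all other protein-coding genes, or for the RNA types against all other annotated genes, with Benjamini-Hochberg (BH) adjustment over the 33 lists and a threshold of 0.05. Of the listed symbols, 14 had no protein-coding match in the annotation. Words of 6 bases, both strands merged, were counted within 50 bp of each summit and in windows shifted by 500 bp to each side, with Fisher's exact test and BH adjustment over 2080 words. Neighbouring genes and overlapping words are not independent, so these p-values are smaller than they would be with independent items. Summit windows and their flanks belong to the same peaks, and the word test did not use this pairing. The comparisons, lists, tests and most alternatives were chosen before the data were examined.

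Items were named by rule: the 15 peaks with the highest signal and the genes whose window held the summit (otherwise the gene holding it, otherwise the nearest 5′ end); up to 4 members per list with the highest-signal peak; for each list past the threshold the number without a peak; C16A3.4 and unc-119 always; and the 5 words most significantly higher and the 3 most significantly lower at summits. Signals given beside list members are those of the thresholded list.

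The alternatives were other promoter windows, peak regions in place of summits, genes with no close neighbour, the strongest 1610 thresholded peaks, the 6440 strongest pooled peaks, other matching distances, other word windows and backgrounds, the ce10 lists, and each replicate's own 3220 strongest peaks in place of the thresholded list (without replicate 1, without replicate 2). Rotation of list membership along the genome, protein-coding genes as background for RNA types, promoter windows matched in G and C content, and the correlation over all matched replicate peaks were added after seeing the data. The setting of genes with no close neighbour did not count genes of piRNAs, a class of small RNAs, as neighbours. All of these piRNA genes stayed in the background of the RNA types under that setting. Peaks of the control itself and of other tagged proteins were not analysed here.

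The code was tested on simulated data. With peaks planted in promoters of 10 lists of 50 genes among 19973, all 10 lists were called, and 1 of 200 random lists was. All 1739 planted promoter peaks were classed as promoter, and 20000 random sites fell in promoters at 1.01 times the rate of random placement. Of 1000 simulated peaks of which 700 were shared with shifts of up to 50 bp, 701 were matched. A word placed in 20% of 3000 windows ranked first of 2080, and 0 words were called when none was placed. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.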

Results

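Chromatin immunoprecipitation followed by sequencing was carried out on first-stage (L1) larvae of Caenorhabditis elegans, taken as whole animals of both sexes. The strain, OP345, carries an integrated transgene, wgIs345, that adds a copy of the gene C16A3.4 fused to green fluorescent protein (eGFP) in an unc-119 mutant background. C16A3.4 is named znf-622 in the reference annotation and encodes a zinc finger protein whose relatives in yeast and human act in the maturation of the large ribosomal subunit. The series holds 1 group of 2 samples, which the labels call biological replicates 1 and 2, so no comparison between conditions exists. The comparisons are between the replicates, between peaks and random positions of the genome, and between lists of genes. The lists give no read counts, so the depth behind each peak is unknown.

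The thresholded list, which the authors derived from the pooled and replicate lists, held 3220 peaks on the ce11 build and covered 1008.4 kb. Of the 15 strongest, 6 had their summits in promoter windows of ribosomal protein genes (rpl-3, rpl-15, rpl-20, rpl-35, rps-12 and rps-20) and 1 in that of iff-2, which encodes the translation factor eIF5A. At rpl-20, rps-12 and rps-20 the nearest 5′ end was that of a neighbouring gene. The signal value per peak is the authors' own, and it ran from 48.4 to 931 with a median of 85.0. The median peak was 344 bp wide, with a range of 86 to 487 bp. All 3220 peaks were the 3220 strongest of the 21096 peaks that the authors called on both replicates pooled, and all shared the highest −log10 q of that list, 3.84, so peaks are ranked here by signal only.

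The strongest peak had its summit at −284 bp from the 5′ end of rpl-3, at chromosome III, positions 3867444 to 3867720, with a signal of 931 in the thresholded list, 400 in replicate 1 and 534 in replicate 2. The second, at chromosome II, positions 10563448 to 10563716 (signal 902), had its summit at −176 bp from cdc-48.1, a member of the AAA ATPase family that extracts ubiquitinated proteins. The peak of rpl-15 and K11H12.8, at chromosome IV, positions 654783 to 655053, had a signal of 805, and that of iff-2 and F54C9.14, at chromosome II, positions 8561297 to 8561560, had a signal of 747. The fifth peak lay between tasp-1 and K01G5.10, at chromosome III, positions 10759106 to 10759403 (signal 711). Peaks at rpl-20 and Y17G9B.5 (signal 677; chromosome IV, 4749938 to 4750206) and at rpl-35 (signal 644; chromosome III, 7854562 to 7854829) followed. Those at rps-12 and ska-3 (chromosome III, 5679015 to 5679256) and at K12H4.5 (chromosome III, 8043842 to 8044122) had signals of 620.1 and 620.0. The peak at rps-20 and ekl-4 (chromosome I, 14469212 to 14469472) had a signal of 551. Replicate 1 and replicate 2 ranked these 10 peaks between 1 and 10 and between 1 and 17 of their own lists.

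The remaining 5 of the 15 strongest peaks had signals of 483 to 524. The peak upstream of puf-9, which encodes a Pumilio-family RNA-binding protein (chromosome X, 5841186 to 5841433), had its summit inside exons of the non-coding genes W06B11.7 and W06B11.9. The peak in the egg-5 promoter window (chromosome I, 4171976 to 4172368; signal 516) had its summit 56 bp from sls-2.4, a spliced leader RNA gene. The peak at chromosome X, positions 11094005 to 11094360 (signal 491), lay in no promoter window, and the nearest protein-coding 5′ end was that of W02H3.3, 3996 bp away. The last 2 had their summits at −223 bp from eelo-2 (chromosome IV, 17249794 to 17250033) and at −301 bp from cox-5A, a subunit of cytochrome c oxidase (chromosome III, 12905076 to 12905325). The other 14 of the 15 summits lay in promoter windows.

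Peaks were concentrated just upstream of protein-coding genes and rare in exons. Of the 3220 summits, 1982 (61.6%, Wilson 95% interval 59.9 to 63.2) lay between 1000 bp upstream and 200 bp downstream of a protein-coding 5′ end. Random placement on the same chromosomes put 21.2% there. Only 66 summits (2.05%, against 23.2% when placed at random) lay in exons outside these windows, 528 (16.4% against 31.0%) in introns and 536 (16.6% against 21.4%) between genes. These 4 shares differed from random placement with an adjusted p of 0.0025 (two-sided permutation test, BH over 5 classes), from an unadjusted p of 0.002, the smallest that 1000 placements can give. The 108 summits in non-coding genes (3.35% against 3.25%, adjusted p = 0.755, permutation test) did not pass the test. The intervals cover counting error in the number of peaks and not the unknown depth.

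**Figure D1:**
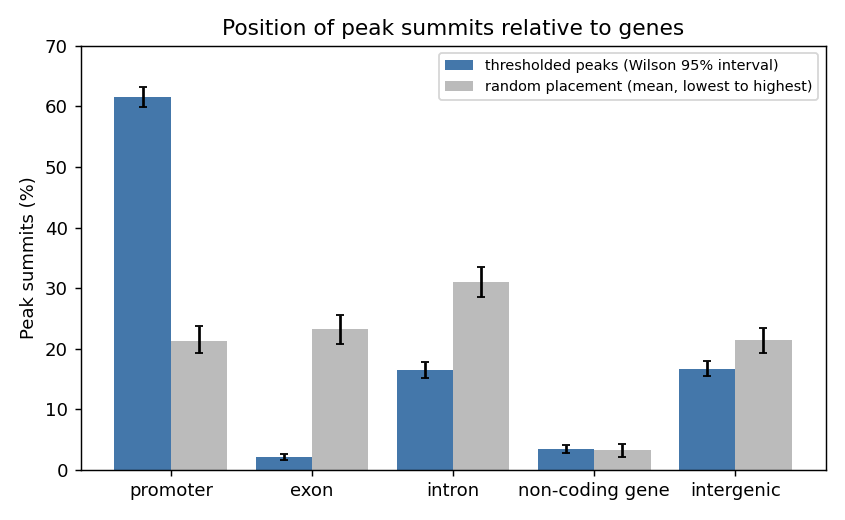
Percent of thresholded peak summits in each class of position (blue, 3220 peaks, bars with Wilson 95% intervals) and percent after random placement on the same chromosomes (grey, mean of 1000 placements, bars from the lowest to the highest). Promoter windows held 61.6% of summits against 21.2% when placed at random, and exons 2.05% against 23.2%.

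Within 1000 bp of the nearest protein-coding 5′ end lay 2135 summits (66.3%), and 1266 (39.3%) lay within 250 bp. The median position of those within 1000 bp was −165 bp, with quartiles at −302 and −62 bp, and 86.5% were upstream. Promoter windows of 2728 of the 19973 protein-coding genes (13.7%) held a summit. A single gene's window held the summit for 1237 peaks and windows of several genes for 745 peaks, so for the latter the signal cannot be assigned to 1 gene. Some summits in the windows of protein-coding list members named below lay inside another gene. Those of col-38, col-185, pas-4, rpt-2, his-24, nhr-47, syd-2, lin-14 and daf-16 lay in exons of non-coding genes. For col-185 a tRNA gene was among them. The summit of nola-3 lay in an intron of fath-1, and those of fars-1 and vha-13 in 3′ untranslated regions of T08B2.15 and cept-2.

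**Figure D2:**
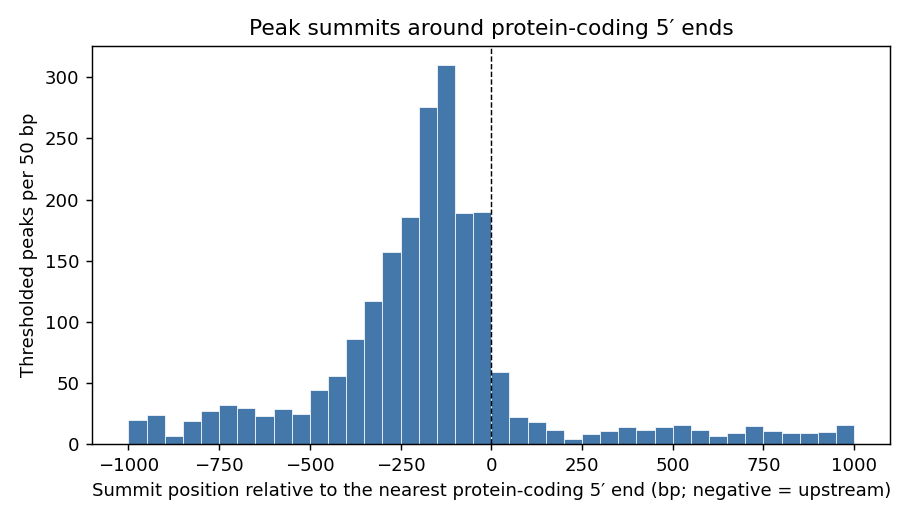
Number of thresholded peak summits per 50 bp (vertical axis) by their distance in bp from the nearest protein-coding 5′ end (horizontal axis, negative upstream, dashed line at the 5′ end), for the 2135 summits within 1000 bp. The median was −165 bp and 86.5% of these summits were upstream.

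Genes that make and run the ribosome carried peaks more often than other protein-coding genes. Among cytosolic ribosomal protein genes, 71 of 81 (87.7%) had a summit in the promoter window, against 13.4% of other protein-coding genes (exact adjusted p = 9.35e-50), and 10 had none. Of 41 translation factor genes, 31 (75.6%) had a peak and 10 had none (exact adjusted p = 2.47e-18). Beside iff-2 they included eef-1A.1, an elongation factor gene (signal 468), eif-3.C (328) and eef-1G (323). Of 38 ribosome biogenesis genes, 20 (52.6%) had a peak and 18 had none (exact adjusted p = 5.55e-08), with the highest signals at lpd-7 (282), fib-1, which encodes fibrillarin (271), nola-3 (228) and rbd-1 (218). Mitochondrial ribosomal protein genes had a peak in 30 of 70 cases (42.9%) and none in 40 (exact adjusted p = 9.72e-09), led by mrps-7 (signal 291), mrpl-55 (271), mrpl-49 (250.3) and mrpl-28 (248). Genes of aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, had a peak in 10 of 32 cases (31.2%) and none in 22 (exact adjusted p = 0.0193), led by ears-2 (signal 233), mars-1 (186), kars-1 (168) and fars-1 (141). Each test was Fisher's exact test, two-sided, with BH adjustment over all 33 lists. With replicate 1's strongest peaks alone the synthetases no longer passed (exact adjusted p = 0.0678). Among genes with no other 5′ end within 1000 bp, neither the synthetases (ratio of shares 2.98 against 2.29 in the main run, exact adjusted p = 0.104) nor ribosome biogenesis (4.01 against 3.87, adjusted p = 0.0928) passed, although neither ratio fell in this smaller set.

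Genes of protein turnover, folding and acidification also carried peaks more often than other protein-coding genes. The proteasome genes had a peak in 23 of 33 cases (69.7%) and none in 10 (exact adjusted p = 1.52e-12), with signals of 401 at rpn-3, 258 at pas-4, 233 at rpt-2 and 211 at rpn-9. Heat shock and J-domain genes had a peak in 20 of 51 cases (39.2%) and none in 31 (exact adjusted p = 1.92e-05). The peak of rpn-3 was also that of the chaperone gene hsp-110, and hsp-60, dnj-9 and hsp-1 had peaks with signals of 297, 274 and 264. Of 20 vacuolar ATPase genes, which encode the proton pump of lysosomes and other compartments, 8 had a peak and 12 had none (exact adjusted p = 0.00898), led by vha-8 (signal 332), vha-1 (203), vha-12 (151) and vha-13 (125).

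Large families of receptor, secreted and enzyme genes carried peaks less often. Only 10 of 1301 chemoreceptor genes (0.769%) had a peak, against 14.6% of other protein-coding genes (exact adjusted p = 2.24e-68), and 1291 had none. The highest signals among them were at srh-16 (216), sri-5 (167), sre-23 (128) and srh-2 (126). Neuropeptide genes had a peak in 2 of 102 cases, nlp-4 (signal 80.7) and flp-23 (53.8), with 100 without a peak (exact adjusted p = 0.000231). Of the detoxification genes (cytochrome P450, glutathione S-transferase and UDP-glucuronosyltransferase families), 10 of 185 (5.41%) had a peak and 175 had none (exact adjusted p = 0.0015), among them gst-27 (signal 208), gst-43 (102), and cyp-33C7 and cyp-33C6, which shared a peak (61.5). Of 172 collagen genes, which build the cuticle, 11 (6.40%) had a peak and 161 had none (exact adjusted p = 0.00898), led by col-38 (signal 255), col-2 (218), col-71 (121) and col-185 (111.5). Of 270 nuclear hormone receptor genes, 23 (8.52%) had a peak and 247 had none (exact adjusted p = 0.0251), among them nhr-142 (signal 219), nhr-68 (210.2), nhr-47 (182) and nhr-48 (133).

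The last 3 of these calls did not hold under every setting. With the 6440 strongest pooled peaks the detoxification genes no longer passed (exact adjusted p = 0.405) and the receptors stood at the level of other genes (ratio of shares 1.01, adjusted p = 1). Without replicate 1 the collagens (exact adjusted p = 0.0628) and the receptors (adjusted p = 0.0505) missed the threshold. Among genes with no other 5′ end within 1000 bp none of the 3 lists passed. The ratio of shares moved towards 1 for detoxification (0.706 against 0.394 in the main run, exact adjusted p = 0.708) and the receptors (0.901 against 0.621, adjusted p = 1), but away from 1 for the collagens (0.343 against 0.466, adjusted p = 0.114). The receptors also missed it when list membership was rotated along the genome, a test chosen after seeing the data that keeps neighbouring genes together (adjusted p = 0.125, permutation test).

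**Figure D3:**
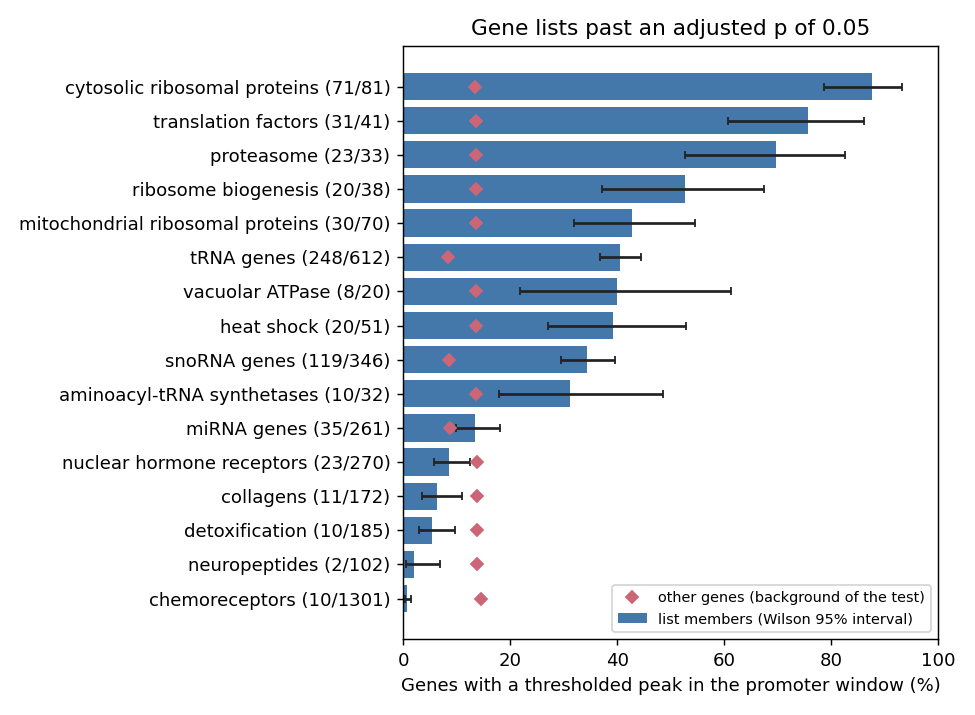
Percent of genes with a thresholded summit in the promoter window (horizontal axis) for the 16 lists with an adjusted p under 0.05 (Fisher's exact test, BH over 33 lists). Bars show list members with Wilson 95% intervals, numbers in brackets the genes with a peak and the members, and diamonds the percent among the other genes of the test; the bars run from 0.769% of chemoreceptors to 87.7% of cytosolic ribosomal proteins.

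None of the remaining protein-coding lists, mostly of tissue and developmental genes, passed the test. Heterochronic genes, which time larval development, had a peak in 5 of 15 cases (exact adjusted p = 0.0684), including ain-1 (signal 280.2), lin-66 (154), lin-14 (102) and lin-28 (75.5). Homeobox genes had a peak in 5 of 87 cases (exact adjusted p = 0.0511), among them ceh-38 (signal 281), ceh-20 (137), ceh-39 (71.0) and ceh-93 (56.2), and none of the 6 Hox genes had a peak (adjusted p = 1). Of the 39 insulin-like peptide genes only ins-39 had a peak (signal 325; exact adjusted p = 0.0629). Neuronal genes had a peak in 4 of 30 cases (snb-1, tbb-1, syd-2 and egl-21; exact adjusted p = 1) and body wall muscle genes in 3 of 30 (unc-112, unc-45 and act-4; adjusted p = 0.931). Intestinal genes had a peak in 1 of 25 cases (erm-1; exact adjusted p = 0.332) and germline genes in 1 of 28 (gld-3; adjusted p = 0.25). Hypodermal genes had none in 25 (exact adjusted p = 0.0666), pharyngeal genes none in 15 (adjusted p = 0.332) and vitellogenins none in 6 (adjusted p = 1). The Hox, pharyngeal and vitellogenin lists are so small that even 0 peaks could not pass (unadjusted p = 0.248 for the pharyngeal genes, Fisher's exact test). Their tests therefore could not show fewer peaks than at other genes. Dauer and insulin signalling genes had a peak in 3 of 20 cases (akt-2, daf-18 and daf-16; exact adjusted p = 0.914), and Wnt and Notch genes in 2 of 20 (wrm-1 and sys-1; adjusted p = 1). The act-4 peak had no replicate 2 summit within 100 bp, and the sys-1 peak had no replicate 1 summit that close. Histone genes had a peak in 10 of 72 cases from 6 separate peaks (exact adjusted p = 0.984), among them his-37 (signal 462), his-24 (142), and his-67 and his-68, which shared a peak (126).

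The calls of 2 of these lists depended on the window. With 500 bp to each side of the 5′ end the homeobox genes (exact adjusted p = 0.0236) and the insulin-like genes (adjusted p = 0.0384) passed, both with fewer peaks than other genes, and with 2000 bp upstream they passed as well (adjusted p = 0.0148 and 0.0188). The homeobox genes also passed with peak regions in place of summits (exact adjusted p = 0.0397) and without replicate 1 (adjusted p = 0.0372).

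Genes of tRNAs and snoRNAs carried peaks often. Of 612 tRNA genes, 248 (40.5%) had a summit in the same window around their 5′ end, against 8.40% of all other annotated genes (exact adjusted p = 1.41e-99), and 364 had none. The highest signals among them were on chromosome X: 216 in the exon of WBGene00014478 (peak at 13307007 to 13307129, in the window of WBGene00014479 as well), 196 at WBGene00014275 (14063869 to 14064212) and 195 inside WBGene00000308 (13665413 to 13665756). Most tRNA genes share sequence with other copies: only 25 of the 612 hold no 36-base word that recurs in the genome, and 3 of these 25 had a peak. Of 346 snoRNA genes, whose products guide RNA modification, 34.4% had a peak and 227 had none (exact adjusted p = 2.03e-39). Their strongest peaks were shared with protein-coding genes: C06A1.9 with cdc-48.1, K11H12.12 and K11H12.13 with rpl-15, and F54C9.12 with iff-2. K11H12.12 and K11H12.13 lie inside rpl-15 and F54C9.12 inside iff-2, so their windows held the promoter peak of the host gene. Against protein-coding genes, a background chosen after seeing the data, both lists passed (odds ratios 4.31 and 3.31, exact adjusted p = 3.94e-57 and 1.31e-21 over 6 lists).

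Of the other 4 RNA types only the miRNA genes passed the test. Of 261 miRNA genes, 35 (13.4%) had a peak, against 8.79% of all other annotated genes (exact adjusted p = 0.0251), and 226 had none, led by cel-mir-354 at the rps-20 peak, cel-mir-5549 at the eef-1A.1 peak, mir-353 (signal 269) and cel-mir-5595 (232). The miRNA call was lost under 7 of the 10 alternatives: against protein-coding genes, with 13.7% (exact adjusted p = 1), without replicate 1 (adjusted p = 0.104), without replicate 2 (0.0881), with 500 bp to each side of the 5′ end (0.0849), with the strongest 1610 peaks (0.12), among genes with no other 5′ end within 1000 bp (0.881) and with list membership rotated along the genome (0.185, permutation test). Among snRNA genes 19 of 129 (14.7%, against 8.80% of the others) had a peak (exact adjusted p = 0.0511), with the spliced leader genes sls-2.4, sls-2.2 and sls-2.1 (signals 516, 434 and 391) and R07E5.16 (252) highest, and with 500 bp to each side of the 5′ end they passed (adjusted p = 0.00798). Long non-coding RNA genes had a peak in 20 of 194 cases (exact adjusted p = 0.566), led by linc-78 (signal 433), linc-108 (219.9), linc-92 (219.0) and linc-60 (153). None of the 20 rRNA genes had a peak (exact adjusted p = 0.332). With so few genes even this lowest possible count could not pass (unadjusted p = 0.251, Fisher's exact test). The test therefore could not show fewer peaks at rRNA genes, and whether reads can be placed uniquely at them was not examined. For all RNA types, the setting with no other 5′ end within 1000 bp left piRNA genes unscreened in the background.

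Chromosome III carried the most peaks for its length and chromosome V the fewest. Chromosome III had 41.7 peaks per Mb, chromosome I 37.8, chromosome II 34.0, chromosome X 33.0, chromosome IV 27.3 and chromosome V 23.7 per Mb. Chromosome X held 584 peaks (18.1%), against 17.7% of the assembled length (density ratio to the autosomes 1.03, exact p = 0.488) and 13.7% of the protein-coding genes (ratio per gene 1.40, p = 1.55e-12). Both p-values are from exact binomial tests, two-sided, which treat peaks as independent. The ratio per gene counts all peaks, 1238 of them in no protein-coding promoter window, so it is not a rate of peaks at genes. With the 6440 strongest pooled peaks X exceeded its share of the length (ratio 1.15, exact p = 1.38e-05), and without replicate 2 the ratio fell below 1 (0.989, p = 0.835).

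The strongest peaks of the replicates coincided at most positions. Of the 3220 strongest peaks of replicate 1, 2160 (67.1%, Wilson 95% interval 65.4 to 68.7) had a summit within 100 bp of a summit among the 3220 strongest of replicate 2. Random placement matched 0.661% on average and 1.12% at most (p = 0.000999, one-sided permutation test, the smallest that 1000 placements can give). Of the 500 strongest peaks, 492 of replicate 1's and 490 of replicate 2's lay within 100 bp of a top-3220 peak of the other replicate. Each replicate list held 30000 peaks, called per replicate with a common control. Over all of them the match was 23.6% against 6.02% by random placement (p = 0.0099, permutation test with 100 placements, the smallest they can give). Of the 3220 thresholded peaks, 3033 (94.2%) had a peak in replicate 1's list and 3180 (98.8%) in replicate 2's.

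Signals of the replicates rose together over the thresholded list. Across the 2996 thresholded peaks matched in both lists, Spearman's rho was 0.625 and Pearson's r of the log2 signals 0.66. Replicate 2's value was the higher at 2425 of them (80.9%); the scale of the signal is not stated, so this may reflect scale or depth. Peaks are not independent replicates, so no p is given. The pooled signal was close to the sum of both replicate signals (median ratio 1.01, quartiles 0.983 and 1.03), so choosing peaks by pooled signal can lower the correlation among them. Across all 7077 matched pairs of the replicate lists rho was 0.75. These relaxed lists hold background, and random placement matched 6.02% of their peaks against the 23.6% observed. Some of the pairs, on which the simulation below also rests, can therefore be chance matches. Among the weakest 1610 thresholded peaks it was −0.311, but simulated pairs with the same signals and an overall rho of 0.75, chosen by their sum in the same range, gave −0.585 (mean of 200 simulations, made after seeing the data), so such a choice alone can give a negative value. The simulated pairs did not match the data closely: chosen as the whole list was, they gave 0.329 where 0.625 was observed.

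**Figure D4:**
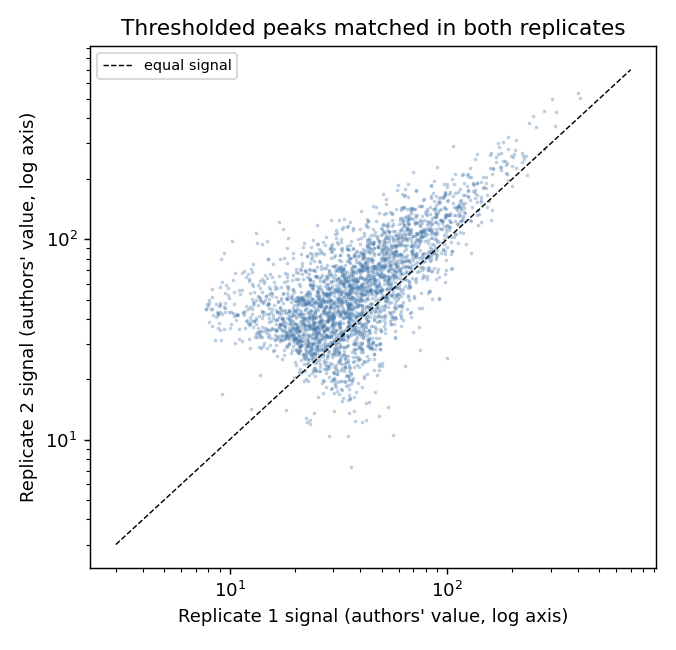
Signal of replicate 1 (horizontal) against signal of replicate 2 (vertical) at the 2996 thresholded peaks matched in both replicates, on log axes and in the authors' signal units, with a dashed line at equal values. Spearman's rho was 0.625, and 2425 peaks lay above the line.

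Sequence at the summits was rich in G and C and in many short words, of which the 5 with the smallest p are named. The word GAGAGA (or its reverse complement TCTCTC) occurred within 50 bp of 24.9% of summits, against 5.37% of windows 500 bp to either side, and AGAGAG in 21.3% against 4.53%. The words ACGCGC (14.8% against 1.37%), GAGCGC (14.9% against 1.89%) and ACGCAG (15.5% against 2.38%) were the other 3. Adjusted p-values of these 5 words ran from 2.08e-158 for GAGAGA to 2.36e-119 for ACGCAG (Fisher's exact test, two-sided, BH over 2080 words). Less frequent at summits were AAAATT (18.4% against 41.0%), CTGAAA (5.22% against 21.9%) and TTAAAA (8.79% against 26.0%), with adjusted p-values of 9.76e-113, 1.54e-110 and 1.06e-95. In all, 763 words were more frequent and 664 less frequent at summits.

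Base composition moved with the words. G and C made up 46.3% ± 7.45 (SD over windows, n = 3220) of the summit windows, 36.3% ± 8.76 (n = 6440) of the flanks and 35.4% of the genome. Against promoter windows without a peak that were matched in G and C content, chosen after seeing the data, AAAATT (ratio 0.974, exact adjusted p = 0.645) and TTAAAA (ratio 1.01, adjusted p = 0.891) no longer differed past the threshold. In that comparison 443 words were more frequent and 684 less frequent at summits, so the less frequent words were the more numerous, unlike against the flanks.

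No thresholded peak lay near the reference position of the tagged gene. Within 20 kb of C16A3.4 (chromosome III, 6381634 to 6382996) there was none, where the mean density of chromosome III predicts 1.73, and the strongest of 6 pooled peaks there ranked 3800. Within 5 kb no list held a peak. Reads from the transgene's copy of C16A3.4 would align to this position too, so the native and the added copy cannot be told apart. The unc-119 gene was examined as the marker of the transgene, which was placed in the mutant strain by unc-119 rescue. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935) lay 1 thresholded peak, ranked 1960, where 1.93 are predicted. It lay at chromosome III, positions 10895855 to 10896198, in an intron of fbxb-87 and with its summit at −336 bp from com-1, and the top 3220 peaks of replicate 2 alone held none in that interval. Within 5 kb of unc-119 there were 0 thresholded and 6 pooled peaks.

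On the older build, ce10, the thresholded list held 3186 peaks, with 564 on chromosome III and 491 on V against 575 and 495 on ce11. The highest signal was 930.3 on ce10. No coordinates were converted between the builds.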

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

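The tests of base composition, of promoters without a peak, of shared sequence, of neighbouring promoters and of isolated genes were set before their results were seen; the tests with other RNA types or other gene lists, the direct test between kinds of tRNA genes and the positions of the peaks in the next paragraph were set afterwards. The series has 1 group, so no biological explanation was tested.

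Some of the 3220 strongest peaks of each replicate had no counterpart in the other, and some pooled peaks fell just below the list that the comparisons rest on. Among the 3220 strongest peaks of replicate 1, 462 had no summit of replicate 2's full list within 100 bp, and among those of replicate 2, 491 had none in replicate 1's. Their median ranks were 2522.5 and 2447, so most were weak members of these sets. Of the 462 and 491 peaks, 73 and 205 still had a thresholded summit within 100 bp, so the sets overlap with the thresholded list. Their summits lay in promoter windows in 40.5% (Wilson 95% interval 36.1 to 45.01) and 39.9% (35.7 to 44.3) of cases. Only 142 and 167 of them also had no overlapping peak region in the other list. In the pooled list, 204 peaks shared the highest q value with the thresholded peaks and fell below the lowest thresholded signal, and 42.6% of these (36.1 to 49.5) lay in promoter windows. The share was 61.6% in the thresholded list and 70.2% in its stronger 1610 peaks, so within that list it rose with signal. Whether weaker signal accounts for the lower shares in the sets above was not tested. The peaks without a counterpart were not compared with matched peaks of equal rank, so these shares cannot separate weak signal from the missing counterpart.

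The first pattern weighed is the excess of peaks at tRNA genes. Protein-coding promoters beside the tRNA genes do not account for all of it: of the 454 tRNA genes with no such window within 200 bp, 34.8% had a summit within 200 bp, against 0.85% of random intervals in similar sequence and 2.42% at most in 1000 placements. Reads shared between near-identical copies stay open as a candidate explanation: only 25 tRNA genes hold no 36-base word that recurs in the genome, and 12% of these (Wilson 95% interval 4.17 to 29.96) carried a peak, against 41.7% of the other 587 (p = 0.00287, Fisher's exact test) and 13.7% of protein-coding genes. Strongly transcribed chromatin that is enriched whatever protein is tagged also could not be excluded. The snoRNA genes carried peaks more often than protein-coding genes, but some lie inside a host gene and share its promoter peak. By promoter window, snRNA genes at 14.7% did not pass the test. By distance, 20 summits lay within 200 bp of an snRNA gene, where random placement gave 1.83 on average and 6 at most. No other tagged protein was analysed here.

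The second pattern is the excess of GAGAGA and ACGCGC, 2 of the 763 words more frequent at summits; the others were not weighed here. Higher G and C content may account for part of it. Against promoter windows without a peak matched in G and C content (46.3% in both sets), an excess remained: GAGAGA was still 2.56 times (24.9% against 9.72%, exact adjusted p = 5.57e-80) and ACGCGC 4.65 times (14.8% against 3.18%, adjusted p = 3.96e-88) as frequent. The matched windows were not screened for exons of neighbouring genes. They can thus differ from summit windows in more than the words, and the comparison does not isolate G and C content. Against unmatched windows placed at random up to 1000 bp upstream of genes without a peak, the ratios were 4.04 for GAGAGA and 13.1 for ACGCGC. Those windows were not matched to the summits in distance from the 5′ end or in promoter activity. The comparison therefore cannot decide whether sequence of active promoters in general accounts for the excess. Whether the tagged protein or another promoter-bound protein meets these words cannot be told from peak lists.

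The third pattern is the excess at cytosolic ribosomal protein genes. Shared promoters of neighbouring genes do not account for it: among genes with no other 5′ end within 1000 bp, 76.2% of 21 ribosomal protein genes had a peak against 7.38% of the others, a ratio of 10.3 (exact adjusted p = 1.37e-13). Promoters that are active in most cells and enriched whatever protein is tagged remain a candidate explanation, since all 4 other lists of such genes tested (proteasome, translation factors, mitochondrial ribosomal proteins and vacuolar ATPase) carried more peaks than other genes. That comparison cannot separate it from binding by the tagged protein, which needs peaks of an unrelated eGFP fusion.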

How the results depend on the processing

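The G and C matched, rotated, protein-coding-background and all-pairs settings were chosen after seeing the data. The number of peaks (3186 on ce10, 3192 merged), the replicate overlap (50.2% to 73.2%), the promoter share (50.2% to 71.4%) and the ratio of peaks per gene on X (1.34 to 1.56) kept their direction and their side of the threshold under every alternative run. Of 16 lists past the threshold, 10 passed under all 10 alternatives: cytosolic and mitochondrial ribosomal proteins, translation factors, proteasome, vacuolar ATPase, heat shock, chemoreceptors, neuropeptides, tRNA and snoRNA genes. The number of lists past the threshold was 10 among genes with no close neighbour, which leaves fewer genes to test, and 14 to 18 otherwise. The number of words more frequent at summits was 443 with G and C matched windows and 645 to 863 otherwise. Spearman's rho of the replicate signals was 0.679 with summits within 50 bp, −0.311 among the weakest 1610 peaks and 0.75 over all matched pairs; simulated pairs chosen by their sum gave −0.585 in the range of the weakest peaks, but 0.329 over the range of the whole list, below the 0.625 observed. The X to autosome density ratio was 1.15 with the 6440 strongest pooled peaks, and 0.989 to 1.07 with 1 replicate left out. The thresholded peak near unc-119 dropped out within 5 kb (0 peaks), and with 1 replicate left out the count within 20 kb was 0 to 1. Ratios of shares crossed 1, with an adjusted p above 0.05 on the new side, for histones (0.96 with the 6440 pooled peaks, 0.94 to 1.06 with 1 replicate left out), nuclear hormone receptors (1.01 with the 6440 pooled peaks), neuronal genes (1.15 with 500 bp to each side, 1.48 without close neighbours, 0.507 to 1.00 with 1 replicate left out), dauer genes (0.43 with 500 bp to each side, 0.741 without close neighbours, 0.762 to 1.13 with 1 replicate left out), body wall muscle and Wnt and Notch genes (1.67 each without close neighbours), snRNA genes (0.881 without close neighbours), and miRNA and long non-coding RNA genes (0.982 and 0.755 against protein-coding genes). Over single lists, words and the promoter ratio, 353 alternative values stayed on their side, 17 lost the call and 7 gained it without crossing 1, and 15 crossed 1, of which 3 also lost the call. The word TTAAAA went to 1.01 with G and C matched windows. Except where stated, the cause was not tested. No paired analysis between conditions was possible because the series has 1 group. Depth is unknown, so the peaks absent from a list cannot be told from peaks missed at its depth.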

Other observations

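Peaks away from protein-coding promoters were at tRNA and snoRNA genes more often than random sites, a count made after seeing the data. Of the 1238 thresholded summits outside promoter windows, 169 (13.7%) lay within 200 bp of a tRNA gene and 55 (4.44%) within 200 bp of a snoRNA gene, where random placement outside promoter windows gave 4.18 and 1.9 summits on average and 9 and 6 at most (p = 0.0099 for both, one-sided permutation test with 100 placements, the smallest they can give). In introns of protein-coding genes, 92 of 528 summits (17.4%) lay that close to a tRNA gene. Over the whole list, 215 summits were near tRNA genes, where random placement gave 8.7 on average and 15 at most, and 80 were near snoRNA genes, where it gave 5.75 on average and 12 at most (p = 0.0099 for both, the same permutation test). Near snRNA genes lay 20 summits, against 1.83 on average and 6 at most (p = 0.0099, the same permutation test). Near miRNA genes lay 8, against 3.53 on average and 8 at most (p = 0.0297, the same permutation test). Peaks near tRNA genes were of middling strength, with a median rank of 1692 of 3220 and a best rank of 239. Those near snoRNA genes were stronger, with a median rank of 902.

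Ribosomal protein promoters made up a larger share of the 500 strongest peaks than of the whole list. Windows of cytosolic ribosomal protein genes held 6 of the 15 strongest summits (Wilson 95% interval 19.8% to 64.3%), 20 of the 100 strongest (13.3% to 28.9%), 46 of the 500 strongest (6.97% to 12.1%) and 68 of all 3220 (1.67% to 2.67%). Translation factor windows held 5 of the 100 strongest summits and 33 of all 3220, and proteasome windows 1 and 24.

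Among the 2080 words, the 3 with the smallest p against promoter windows matched in G and C content were ACGCGC, GAGCGC and GAGAGA. Of the 443 words more frequent at summits in that comparison, 370 were also more frequent against the flanks. CTGAAA, whose reverse complement TTTCAG resembles the end of worm introns, was less frequent at summits in that comparison too (5.22% against 12.3%, exact adjusted p = 4.98e-29). The matched windows were not screened for neighbouring genes, so they may hold intron ends.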
